A study of Mus musculus with 19 samples.

How the data were processed

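Expression was measured on 2-colour arrays in FDCPmix cells, a mouse haematopoietic progenitor line that grows in interleukin-3 and can form several blood lineages. The labels also carry the words ES cell line, which the sources used here do not explain. Each of the 19 arrays paired the RNA of a treated culture, its own RNA, with a reference RNA from non-treated cells or, in the time course, from treated cells at 0 h. The 5 groups were treated cells without a stated time (4 arrays) and cells at 3 h (4 arrays), 7 h (4 arrays), 12 h (4 arrays) and 23 h (3 arrays) after tamoxifen, a ligand of the oestrogen receptor. In each group of 4, the own RNA was labelled with Cy5 on 2 arrays and with Cy3 on 2 arrays. At 23 h it was in Cy5 on 1 array and in Cy3 on 2. Replicate 2 at 23 h was not analysed here.

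Total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5, per the labels' protocols. The same protocols mention organs and pooled control animals, which does not match a cell line, so the reference was taken from each sample's own channel labels. The authors deposited 1 log ratio per spot, treated here as log2 because its extremes lie near the log2 range of scanner signals. The base, the numerator and the normalization are not given in the sources used here. Most deposited columns were centred: the column medians were 0.006, -0.012, 0.014 and 0.024 for treated replicates 1 to 4 and -0.002, -0.0105, 0.005 and 0.01 for 3 h replicates 1 to 4. They were -0.007, -0.003, 0.01 and -0.009 for 7 h replicates 1 to 4, -0.002, -0.003, -0.004 and 0.008 for 12 h replicates 1 to 4, and 0, 0.233 and 0.003 for 23 h replicates 1, 3 and 4. Because 1 column lay further than 0.1 from 0, every array was centred on its median. Scale, base and direction stay unknown, so fold sizes hold only if the base is 2.

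Each array held 1 extreme value, between 16.276 and 17.031 or between -16.725 and -16.235, that was repeated on 8 to 29 spots. These values were read as spots with a channel at its floor and set to missing. Keeping them was tried as an alternative after the data were seen. Between 19658 and 19841 of the 20205 probes had a value on the treated arrays and between 20088 and 20158 on the others. No spot intensities or backgrounds were used here, and the number of arrays limits the precision. No pair of arrays shared more than 0.289% of their values.

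The direction was not settled by the labels, and the rule fixed for it before the data were examined was not followed. That rule correlated arrays of opposite dye within a group, after removing each dye's mean, and kept the deposited signs only if the mean correlation was positive. The mean was -0.02 by Pearson (permutation p = 0.0279 over 10000 permutations) and -0.02 by Spearman (permutation p = 0.37). Read by its sign alone, the rule asks for changing the sign of every array with the own RNA in Cy3. The deposited signs were kept because the repeated extreme value is positive with the own RNA in Cy5 and negative with it in Cy3, on every array except 7 h replicate 4. A floored channel would give 1 fixed sign by dye if the columns had not been turned to put the own RNA on 1 side. This choice was made after the data were seen, and it favours the gene list findings. The counts of the fit described here, those with array weights and those without both arrays in doubt are therefore given under both readings; counts under the other alternatives hold for the deposited signs. Which RNA is the numerator also stays open. That sign would make the own RNA the numerator only if Cy3 is the channel at its floor, which was not checked. Higher and lower therefore mean higher and lower in the own RNA under an assumed direction. Over all probes, the lowest Pearson correlation between arrays of the same orientation and group was -0.15. The mean Spearman correlation of same-dye arrays was 0.15 within a group and 0.06 between groups. For arrays of opposite dye it was -0.025 within a group and -0.027 between groups. Under the deposited signs, arrays of opposite dye were thus no more alike within a group than between groups.

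The arrays 7 h replicate 4 and 23 h replicate 3 are in doubt. The repeated extreme value of 7 h replicate 4 has the sign opposite to its dye label. Replicate 3 at 23 h has the deposited median of 0.233, and its values run against its group, a trait found only from its outcome. Its repeated extreme value, -16.61, has the sign that fits its dye label. Both arrays were kept, and fits without them or with their signs turned were added after the data were seen.

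Probe annotation came from the platform table: 13891 probes had 1 gene symbol, 5 had several and 6309 had none. Of the first, 13855 matched a RefSeq gene ID, all with the same symbol. Probes of 1 gene were averaged, which concerned 2969 of 9834 genes, and probes without a single symbol were kept by probe number, giving 16148 features. A feature was tested if it had values on at least 3 arrays of a 4-array group, or 2 of the 3-array group, in both dye orientations.

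Tests used limma 3.58.1 in R 4.3.3. A single fit covered all arrays, with a coefficient per group and a dye term, followed by empirical Bayes moderation (prior degrees of freedom 2.46, residual degrees of freedom up to 13). All tests were two-sided, adjusted by Benjamini-Hochberg within a comparison and called at an adjusted p under 0.05. Coefficients against 0 compare the own RNA with the reference RNA, which leaves out the reference's own spread. In the time course that reference is labelled as treated cells at 0 h, not as non-treated cells. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Gene errors are the fit's standard errors unless given as an SD over arrays.

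The 38 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01. It was repeated with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way without setting them against other genes. Camera ran on the 14855 features measured on every array, because it takes no missing values. No list call held with an estimated correlation in any comparison. Named genes followed a fixed rule: the 12 largest rises and 12 largest falls among called genes with the same direction on every array, or 10 by unadjusted p where fewer were called. Esr1 was to be given whenever measured, as were Hoxb4 and Myc, which are not among the features here. The rule also named members of lists. Their number was lowered from at most 4 to 2 per list, and those of other cell types were limited to the erythroid, megakaryocyte, lymphoid, pluripotency and fibroblast lists, after it was seen how many names arose.

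The fit was tested on simulated data with 200 changed features. At a log2 change of 0.5, 1 and 2 it recovered 62.7%, 88.1% and 93.9% in the treated group, 55.2%, 94.0% and 98.5% at 3 h, 58.2%, 92.5% and 97.0% at 7 h, 61.2%, 83.6% and 98.5% at 12 h and 34.3%, 85.1% and 97.0% at 23 h. For 23 h against 3 h it recovered 20.9%, 61.2% and 90.9%. The same simulation also called 676 unchanged features in the treated group, where the arrays vary most, and 0 to 3 in the other comparisons. In 20 simulated sets without change at 12 h, camera called 0 lists, and it found a glycolysis list shifted by -0.2 in 20 of 20. These sets had independent genes, so they do not show how camera behaves where members of a list vary together. With no change but the treated arrays' larger spread, the treated comparison falsely called 414 to 506 features in 5 draws, and with the other groups' spread it called 0.

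Alternatives covered the dye term, the replicate number as a block, centring, scaling, quantile normalization, missing values, single probes, robust moderation, array weights, the arrays in the fit, 1 dye orientation at a time, a 1.5-fold limit and each array left out in turn. Added after the data were seen were the other reading of the signs, for named genes and the correlation between times too, the arrays in doubt, fits on the 15 time-course arrays, the repeated extreme values kept, camera on all tested features, and lists under scaling and quantile normalization.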

Results

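Gene expression was followed in FDCPmix cells after tamoxifen, with treated cells at 0 h or non-treated cells as reference. There were 4 arrays of treated cells without a stated time, 4 each at 3 h, 7 h and 12 h, and 3 at 23 h. The treated arrays were the most spread: their SD over spots was 0.619 to 0.642, against 0.235 to 0.36 on the others, and the median SD between arrays of a group was 0.30 against 0.15 to 0.16. All values are log2 ratios of the own RNA to the reference, if the deposited base is 2 and the own RNA is the numerator, which is assumed. The number of arrays limits the precision, and the sign reading on which directions rest departs from the rule fixed beforehand.

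The treated cells without a stated time were compared with non-treated cells. Among the genes called lower was Bnip3, a mitochondrial protein of mitophagy and cell death, at -1.38 (SE 0.22, n = 4, adjusted p = 0.00488). Selenbp2, a selenium-binding protein, stood at -1.48 (SE 0.25, n = 4, adjusted p = 0.00675), and Ndrg1, a stress-responsive gene, at -1.20 (SE 0.27, n = 4, adjusted p = 0.0244). Zfyve1 stood at -1.20 (SE 0.20, n = 4) and Pi4kb, a phosphatidylinositol kinase, at -1.18 (SE 0.15, n = 4). Other called falls were Psmb8, an immunoproteasome subunit (-1.60, SE 0.39, n = 3), Bdh2 (-1.43, SE 0.37, n = 4) and EG245190 (-1.38, SE 0.31, n = 3). Also lower were catalase, Cat (-1.34, SE 0.34, n = 3), the DNA glycosylase Mbd4 (-1.33, SE 0.32, n = 4), Ddx55 (-1.29, n = 4) and the granzyme Gzmc (-1.29, SE 0.33, n = 4). The largest rises were Ell, a transcription elongation factor, at 2.18 (SE 0.35, n = 3, adjusted p = 0.00649) and Glrx5, a glutaredoxin of iron-sulphur cluster assembly, at 2.08 (SE 0.39, n = 3, adjusted p = 0.0127). Sema3g, a semaphorin, rose by 1.36 (SE 0.16, n = 4, adjusted p = 0.000786). Mtus1 rose by 1.64 (SE 0.21, n = 4, adjusted p = 0.00100) and H1f7, a linker histone of the testis, by 1.51 (SE 0.23, n = 4). Further called rises were Rhox13 (2.04, n = 4), Retreg2 (1.78, n = 3), Actn2, an alpha-actinin of muscle (1.78, n = 4), Papolb (1.61, n = 3), Sec16b (1.57, n = 4), Klhdc7a (1.48, n = 3) and Fam170b (1.37, n = 4). Esr1, the oestrogen receptor that binds tamoxifen, stood at -0.09 (adjusted p = 0.503). The standard errors given here use the spread pooled over all groups. The SD over the treated arrays was 1.55 for Ell, 1.83 for Glrx5, 1.77 for Psmb8, 1.82 for Actn2, 0.71 for Mtus1 and 0.63 for Sema3g. For these genes the standard errors understate the spread of the treated arrays.

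Several of these values moved by over 1.5 times without 1 array. Replicate 2 carried Sec16b (0.70 without it, adjusted p = 0.103), Cat (-0.57, adjusted p = 0.119) and part of Rhox13 (1.20). Replicate 3 carried Psmb8 (-0.69 without it, adjusted p = 0.0769) and Fam170b (0.60). Replicate 4 carried Bdh2 (-0.90 without it, adjusted p = 0.151), Actn2 (0.90), Klhdc7a (0.69), Ddx55 (-0.68) and EG245190 (-0.61), and replicate 1 carried Gzmc (-0.56 without it). Other calls ended with fewer arrays while the value moved by less. Bdh2 and Ddx55 stood at -1.23 and -1.18 without replicate 1 (adjusted p = 0.109 and 0.0611) and Sec16b at 1.72 without replicate 3 (adjusted p = 0.0582). Papolb stood at 1.11 and 1.46 without replicate 3 or 4 (adjusted p = 0.0875 and 0.0645), and Ndrg1 at -1.11 and -1.10 (adjusted p = 0.0557 and 0.0617). Mbd4 stood at -1.26, -1.10 and -1.19 without replicate 2, 3 or 4 (adjusted p = 0.0543, 0.0863 and 0.0787). Of 37 named genes called in the treated cells, list members included, 22 kept the call in every fit without 1 array that could test them. Among these, Ell, Glrx5, Retreg2, Klhdc7a and EG245190 had values on 3 treated arrays and were tested in 3 such fits. In 1 of the 3 the array left out was the one without a value, so these genes were not tested without each array. With the sign of the Cy3 arrays changed, 23 of the 37 had the opposite direction, and 0 kept a call in the same direction. Ell, Papolb and Psmb8 were then called the other way (-1.69, -1.51 and 1.52), and Bnip3, Ndrg1 and Selenbp2 stood at 0.32, 0.31 and 0.039. The largest rises and falls were chosen for lying on the same side on every array under the deposited signs. Turning the Cy3 arrays sets such values against each other. Lost calls and turned directions are therefore largely built in and do not weigh the 2 readings.

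In all, limma called 758 of 15915 features in the treated cells, 380 higher and 378 lower, and 3500 had an unadjusted p under 0.05. Of the called features, 449 had a gene symbol that is not a clone name, and 361 of these lay on the same side on every array. The count rests on a spread pooled with the calmer arrays of the other groups. With each array weighted by its own spread limma called 2 features (34 with the Cy3 signs also changed), and with only the treated arrays in the fit 0 (982 at an unadjusted p under 0.05). It called, with arrays scaled to the same spread 5 (4 higher, 1 lower) and with quantile normalization 3 (2 higher, 1 lower). With only the Cy5 arrays it called 509 (172 higher, 337 lower) and with only the Cy3 arrays 488 (416 higher, 72 lower). Simulated arrays with no change and the treated arrays' spread gave 414 to 506 false calls. The count was 1396 without replicate 2 and 1313 with the sign of the Cy3 arrays changed (352 higher, 961 lower), of which 20 features were called under both readings, 6 of them in the same direction.

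Genes of glycolysis lay low in the treated cells: 11 of 15 measured members were below 0, with a list median of -0.37 and array medians of -0.24, -0.23, -0.41 and -0.39. Of these genes, 3 fell and 0 rose over all features (9 fell adjusted over the list alone), among them the glucose transporter Slc2a3 (-0.98, SE 0.18, n = 4, adjusted p = 0.00893) and the phosphoglycerate mutase Pgam1 (-0.45, SE 0.10, n = 4, adjusted p = 0.0253). The list was called by camera (adjusted p = 0.00153), with adjusted p = 0.282 with an estimated correlation. The cholesterol list had a median of -0.27 and 12 of 16 members below 0 (adjusted p = 0.00446, and adjusted p = 0.215 with an estimated correlation). In it 6 genes fell and 2 rose (7 and 2 adjusted over the list alone), with Hmgcs1, an enzyme of the mevalonate pathway, at -0.67 (SE 0.13, n = 4) and Srebf2, the transcription factor of sterol synthesis, at -0.35 (SE 0.06, n = 4). Pgam1 lost its call without replicate 3 or 4 (-0.43 and -0.40, adjusted p = 0.0522 and 0.066), and the cholesterol list without replicate 3 (mean -0.19, adjusted p = 0.0570). The mean of the glycolysis list moved from -0.29 to 0.00881, and that of the cholesterol list from -0.21 to 0.0392, with the sign of the Cy3 arrays changed.

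The G2 and M phase list lay higher in the treated cells, with a median of 0.16 and 31 of 38 members above 0 (adjusted p = 0.00388, and adjusted p = 0.0809 with an estimated correlation). In it 1 gene rose and 1 fell (7 and 2 adjusted over the list alone): Incenp, of the chromosomal passenger complex, at 0.58 (SE 0.16, n = 4) and the phosphatase Cdc25b at -0.42 (SE 0.10, n = 4). Oxidative phosphorylation genes had a median of 0.10 with 61 of 77 above 0 (adjusted p = 0.00634, and adjusted p = 0.389 with an estimated correlation). Of them 2 rose and 1 fell (3 and 2 adjusted over the list alone), with Atp5k at 0.39 (SE 0.07, n = 4) and Cox6b2 at -0.55 (SE 0.12, n = 4). The proteasome list had a median of 0.10 and 29 of 37 above 0 (adjusted p = 0.00472, and adjusted p = 0.383 with an estimated correlation). In it 1 gene rose and 1 fell, over all features and adjusted over the list alone: Psmb7 at 0.22 (SE 0.06, n = 4) and Psmb8 at -1.60. Single arrays ended all 3 list calls: G2 and M phase without replicate 2 (adjusted p = 0.0575) and oxidative phosphorylation without replicate 1, 2 or 4 (adjusted p = 0.192, 0.107 and 0.0950). Their means then stayed within 1.5 times of the full value. The proteasome call ended without replicate 2 or 4 (adjusted p = 0.0575 and 0.376, with a mean of 0.08 in place of 0.13 without replicate 4). Single arrays also ended the calls of Incenp (replicate 1 or 4, 0.40 and 0.36), Cdc25b (3 or 4, adjusted p = 0.0907 and 0.0703) and Cox6b2 (1, adjusted p = 0.0732). They ended those of Psmb7 (1, 2 or 4, adjusted p = 0.0570, 0.0646 and 0.0898) and Psmb8 (3, -0.69).

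Markers of other cell types did not move as lists in the treated cells. Adjusted p was 0.774 for the erythroid list (0 of 16 members called), 0.998 for the megakaryocyte list (1 rose and 1 fell of 7) and 0.998 for the lymphoid list (1 fell of 13). It was 0.210 for the pluripotency list (1 fell of 14) and 0.406 for the fibroblast list (1 fell of 22). Adjusted over the list alone these were 0, 1 rose and 2 fell, 1 fell, 3 fell, and 1 rose and 2 fell. Gp5, a platelet glycoprotein, rose by 0.93 (SE 0.19, n = 4), and by 0.56 without replicate 3. Klf2 stood at -0.32, Lox, a collagen cross-linking enzyme, at -0.33 and Cd3g, a chain of the T cell receptor complex, at -0.36. Lox lost its call without replicate 3 (adjusted p = 0.0656) and Cd3g without replicate 1 or 2 (adjusted p = 0.0873 and 0.114). Klf1, an erythroid transcription factor, stood at -0.53 and missed the threshold (adjusted p = 0.0697), which it passed without replicate 3 (-0.82, adjusted p = 0.00152). Under the other reading of the signs, with the Cy3 arrays changed, 4 lists were called in place of 5. They were lymphoid (median -0.23), ribosomal proteins (0.11), oxidative phosphorylation (0.11) and cytoskeleton (0.11).

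**Figure D1:**
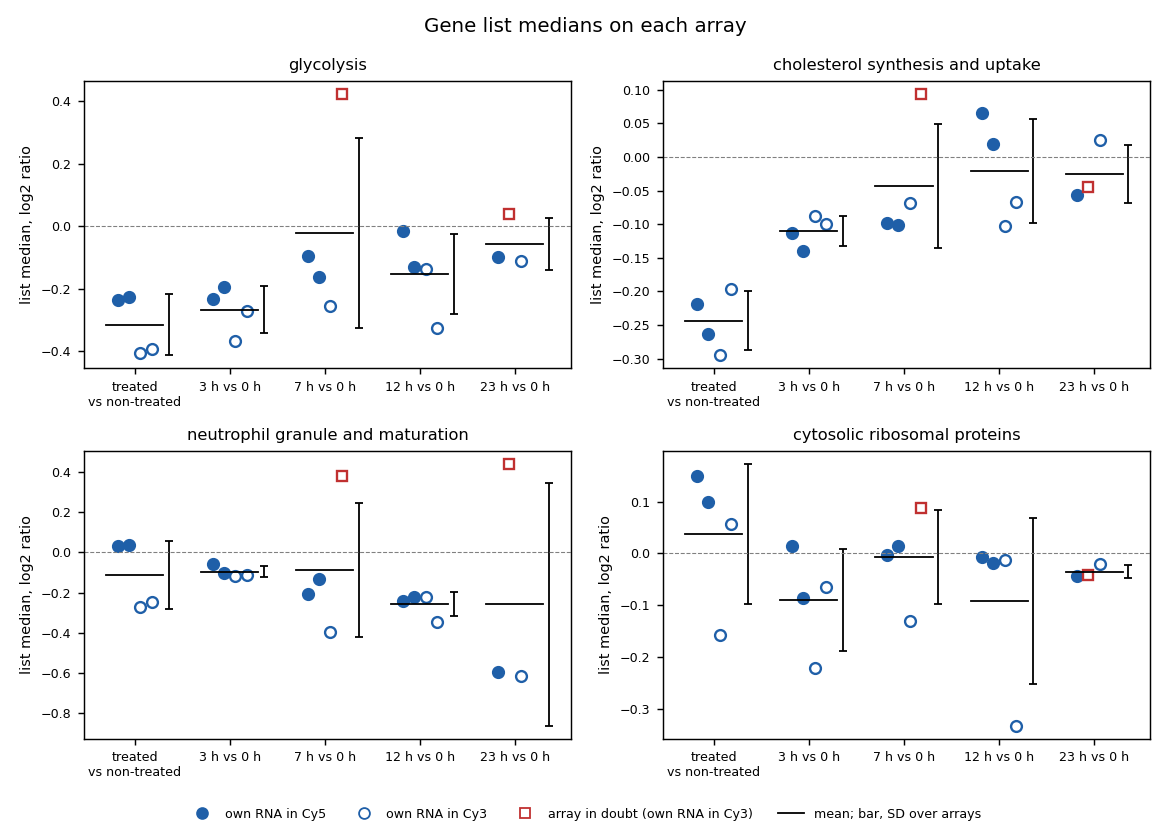
Median log2 ratio of 4 gene lists on each array (vertical axis) by group (horizontal axis): filled circles have the own RNA in Cy5, open circles in Cy3, red squares are the arrays in doubt, the line is the group mean and the bar its SD over arrays. The glycolysis medians lie between -0.41 and -0.20 on all treated and 3 h arrays, while 7 h replicate 4 stands at 0.42 and, for the neutrophil list, 23 h replicate 3 at 0.44.

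At 3 h after tamoxifen, genes of glycolysis lay below the 0 h level: 15 of 16 measured members were under 0, the list median was -0.24, and the 4 arrays had medians of -0.23, -0.20, -0.37 and -0.27. No member passed over all features, and 6 fell adjusted over the list alone, with Tpi1, the triosephosphate isomerase, at -0.48 and Pgam1 at -0.39. Camera called the list (adjusted p = 7.55e-07), with adjusted p = 0.118 with an estimated correlation. The cholesterol list had a median of -0.11 (adjusted p = 0.00208, and adjusted p = 0.118 with an estimated correlation). No member passed over all features, 1 fell adjusted over the list alone, and Fdps, the farnesyl diphosphate synthase, stood at -0.48 and Lpin1 at -0.16.

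Ribosomal protein genes at 3 h had a median of -0.09 with 47 of 58 below 0 (adjusted p = 2.55e-07, and adjusted p = 0.354 with an estimated correlation), for example Rps18 at -0.23 and Rpl7 at -0.30. Cytoskeleton and adhesion genes lay below 0 in 30 of 38 cases (adjusted p = 0.00162, and adjusted p = 0.354 with an estimated correlation), among them the actin-bundling protein Lcp1 at -0.34 and Vasp at -0.22. The list of interleukin-3 and STAT5 targets had a median of -0.08 with 15 of 20 below 0 (adjusted p = 0.0303, and adjusted p = 0.225 with an estimated correlation), with the feedback inhibitor Cish at -0.42 and the survival factor Mcl1 at -0.23. G2 and M phase genes had a median of 0.07 with 27 of 38 above 0 (adjusted p = 0.0174, and adjusted p = 0.118 with an estimated correlation), with Cks2 at 0.28 and Kif23 at 0.16. In these 4 lists 0 members passed, over all features or adjusted over the list alone. The interleukin-3 list lost its call without any 1 array (adjusted p up to 0.135), although its mean stayed between -0.0896 and -0.0768 (-0.0852 in full), and the G2 and M phase list without replicate 3 or 4 (adjusted p up to 0.283, with a mean of 0.0447 in place of 0.0674 without replicate 3). With the sign of the Cy3 arrays changed, 0 of the 6 lists were called at 3 h and the mean of the glycolysis list was 0.0575.

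No single gene passed at 3 h: limma called 0 of 16108 features (865 at an unadjusted p under 0.05, smallest adjusted p 0.188), and 0 with the sign of the Cy3 arrays changed. Under that reading 11 of the 28 genes named at 3 h had the opposite direction, Bnip3 at 0.33, Ndrg1 at 0.12 and Selenbp2 at 0.26 among them. The gene nearest the threshold was Bnip3 at -1.38 (SE 0.22, n = 4, adjusted p = 0.188). After it came Scd2, a fatty acid desaturase, at -0.49 (SE 0.09, n = 4, adjusted p = 0.406), Parp16 at -0.35 and Pgm1, a phosphoglucomutase, at -0.71 (both adjusted p = 0.607). Next came the splicing regulator Nsrp1 at -1.79, Selenbp1 at -0.95, the nucleolar protein Nop58 at 0.32, Selenbp2 at -1.06, Ykt6 at 0.29 and Ndrg1 at -1.15 (adjusted p = 0.676 to 0.734). Hba-a1 stood at -0.28, Itga2b at -0.18, Gata3 at 0.13, Klf2 at 0.12, Acta2 at -0.15 and Esr1 at -0.06 (0.00811 without replicate 3), all short of the threshold. With array weights 3 features were called. Without the 2 arrays in doubt, which belong to other times and enter only through the shared spread and dye term, 18 were called, and 0 with the Cy3 signs also changed.

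**Figure D2:**
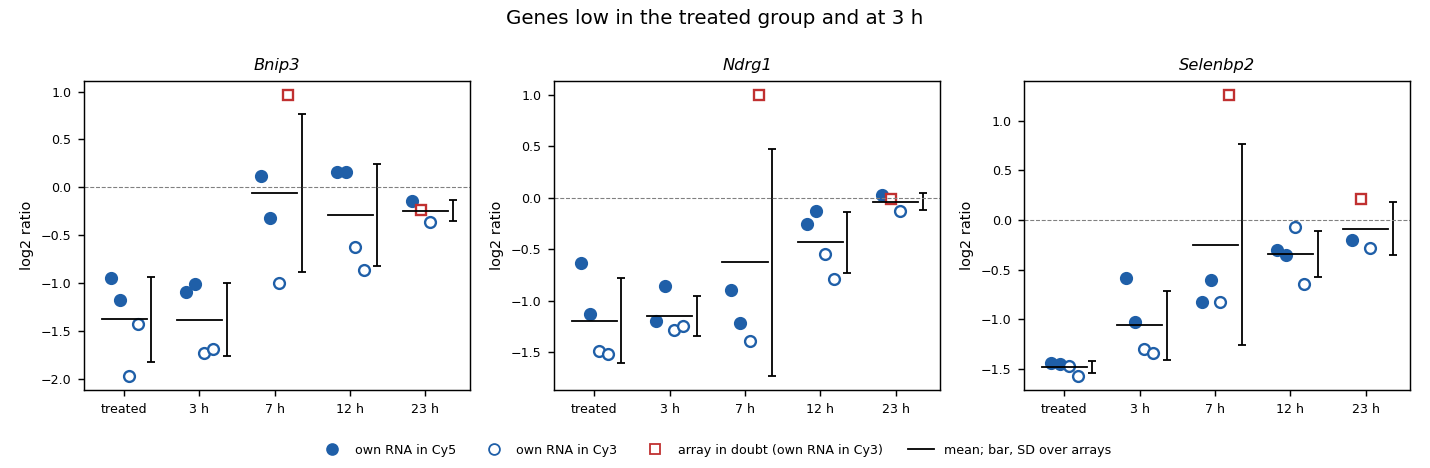
Log2 ratio of Bnip3, Ndrg1 and Selenbp2 on each array (vertical axis) by group (horizontal axis), with the markers, lines and SD bars of the plot of list medians. Mean values in the treated group were -1.38, -1.20 and -1.48, where all 3 genes were called, and at 3 h -1.38, -1.15 and -1.06, where none was; all 6 means lie above 0 with the sign of the Cy3 arrays changed.

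At 7 h, heat shock and chaperone genes lay above 0 in 20 of 22 cases, with a list median of 0.10 (adjusted p = 0.000896, and adjusted p = 0.101 with an estimated correlation). The mitochondrial chaperone Hspa9 stood at 0.14 (SE 0.06, n = 4) and the chaperonin subunit Cct3 at 0.21 (SE 0.09, n = 4), and 0 members passed over all features or adjusted over the list alone. This was the only list called of 38, and the call ended without replicate 3 (adjusted p = 0.324). Without replicate 4, an array in doubt, 9 lists were called, and with the sign of the Cy3 arrays changed 0.

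Among single genes at 7 h, the kinase Mapkapk2 was nearest the threshold at 0.45 (SE 0.09, n = 4, adjusted p = 0.744). It was followed by Fbxl12 at -0.31, the fatty acid dehydrogenase Acadvl at -0.50, Tchp at 1.52, Spaca7 at -0.61, Cldn3 at -0.41, Zdhhc15 at 0.56, Septin12 at 0.53, Tmem252 at 0.25 and Lin7a at -0.50. Values for Hba-a1 (-0.27), Vwf (0.08), Cd3g (-0.15), Lin28a (-0.23), Col3a1 (0.13) and Esr1 (0.05) also missed it. In total limma called 0 of 16087 features (542 at an unadjusted p under 0.05), 0 with array weights, and 0 with the sign of the Cy3 arrays changed. The count was 1 without replicate 3, 4 without replicate 4, and 35 without both arrays in doubt (2 with the Cy3 signs also changed). Of the 18 genes named at 7 h, 8 had the opposite direction with the Cy3 signs changed.

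At 12 h the kinase Clk4, which acts on splicing factors, rose by 1.52 (SE 0.19, n = 3, adjusted p = 0.00457). Of the other called features, probe 8896 rose by 2.03 (adjusted p = 0.00457) and probe 13060 fell by 1.41 (adjusted p = 0.00393); neither has a gene name, and both were named after their values were seen. Smc4, a condensin subunit, stood at 0.73 (SE 0.12, n = 4) and missed the threshold (adjusted p = 0.0915). Also short of it were the dehydrogenase Acadl at 0.94, the syndecan Sdc1 at -0.65, Yrdc at 0.29 and M1ap at -1.38. So were the calcium-binding protein S100a6 at -0.80, the pantothenate kinase Pank1 at 1.05, Tspyl5 at 0.78 and Ftsj3 at -0.25. Values of Nfe2 (-0.23), Vwf (-0.09), Dntt (-0.29), Col3a1 (0.12) and Esr1 (0.04) missed it as well.

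The 3 calls at 12 h were out of 16089 features (565 at an unadjusted p under 0.05). Clk4 lost its call without replicate 3 or 4 (adjusted p up to 0.0661), Sdc1 passed without replicate 4 (-0.89, adjusted p = 0.00639), and the count was 2, 1, 2 and 6 without replicates 1 to 4. It was 42 with array weights and 26 without both arrays in doubt (614 and 2 with the Cy3 signs also changed), and 0 with only the 12 h arrays in the fit. It was 3 with the sign of the Cy3 arrays changed, of which 0 were the same features. Clk4 then stood at -1.01, and 20 of the 34 genes named at 12 h had the opposite direction.

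Genes of neutrophil granules lay low at 12 h, with a list median of -0.28, 12 of 16 members below 0 and array medians of -0.24, -0.22, -0.22 and -0.35. The collagenase Mmp8 stood at -0.76 (SE 0.27, n = 4) and S100a8, a subunit of calprotectin, at -0.52. Camera called the list (adjusted p = 4.63e-05, and adjusted p = 0.334 with an estimated correlation). The monocyte and macrophage list had a median of -0.10 with 17 of 23 below 0 (adjusted p = 0.000936, and adjusted p = 0.0758 with an estimated correlation), with the lysozyme Lyz2 at -0.73 (SE 0.25, n = 4) and the Fc receptor Fcgr3 at -0.18. No member of either list passed, over all features or adjusted over the list alone. Both list calls held without each array in turn, and with the sign of the Cy3 arrays changed neither list was called, with a mean of 0.0393 for the neutrophil list.

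Another list below 0 at 12 h was that of ribosomal proteins (median -0.09, 51 of 58 below 0, adjusted p = 4.97e-11, Rps15a -0.26, Rps27 -0.19). So were cytoskeleton (median -0.06, 27 of 38, adjusted p = 4.63e-05, Tmsb4x -0.36, S100a6 -0.80) and glycolysis (median -0.12, 12 of 16, adjusted p = 0.00267, Hk2 -0.52, Gapdh -0.30). Below 0 were also the unfolded protein response (median -0.06, 21 of 30, adjusted p = 0.0142, Xbp1 -0.37, Slc7a5 -0.50). The same held for immediate early genes (median -0.06, 13 of 18, adjusted p = 0.0320, Klf6 -0.40, Klf2 -0.16) and interleukin-3 targets (median -0.02, 12 of 20, adjusted p = 0.0364, Csf2rb2 -0.37, Pim1 -0.30). Above 0 were G1 and S phase genes (median 0.07, 26 of 38, adjusted p = 0.00267), with the replication clamp Pcna at 0.56 (SE 0.17, n = 4) and the helicase subunit Mcm6 at 0.24, and oxidative phosphorylation genes (median 0.03, 56 of 78, adjusted p = 0.0357, Ndufa2 0.31, Atp5b 0.21). With an estimated correlation, adjusted p was 0.334 for the ribosomal, cytoskeleton, glycolysis, unfolded protein and interleukin-3 lists, 0.342 for immediate early, 0.261 for G1 and S phase and 0.587 for oxidative phosphorylation. In these 8 lists 0 members passed over all features, and adjusted over the list alone only 1 cytoskeleton gene did, falling.

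Each of these 8 calls ended without at least 1 array at 12 h, and means are given where they moved by over 1.5 times. Without replicate 4 the ribosomal list had a mean of -0.02 in place of -0.09 (adjusted p = 0.0905), and the glycolysis call also ended (adjusted p = 0.122). So did those of the cytoskeleton list, with a mean of -0.0682 in place of -0.107 (adjusted p = 0.0867), and the unfolded protein list, with -0.0304 in place of -0.0789 (adjusted p = 0.418). The G1 and S phase call ended without replicate 3 (adjusted p = 0.0619), immediate early without replicate 1, 2 or 4 (up to 0.322), interleukin-3 targets without replicate 1, 3 or 4 (up to 0.533) and oxidative phosphorylation without replicate 1, 2 or 3 (up to 0.634). The interleukin-3 mean was -0.0387 in place of -0.0674 without replicate 4, and the oxidative phosphorylation mean 0.0208 without replicate 3 and 0.0663 without replicate 4, in place of 0.0385. At 12 h 2 lists were called in place of 10 with the sign of the Cy3 arrays changed, ribosomal proteins (median 0.08) and oxidative phosphorylation (0.05), both above 0.

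At 23 h, neutrophil granule genes had a list median of -0.29 with 13 of 16 below 0, for example the lactoferrin gene Ltf at -0.54 (SE 0.31, n = 3) and S100a8 at -0.29. Without replicates 1, 3 and 4 in turn Ltf stood at -0.20, -1.26 and -0.11, and S100a8 at 0.0896, -0.61 and -0.26, so the direction of S100a8 turned without replicate 1. Array medians were -0.60 and -0.62 on replicates 1 and 4, and 0.44 on replicate 3, an array in doubt. The list was called (adjusted p = 0.00722, and adjusted p = 0.545 with an estimated correlation), but not without replicate 1 or 4 (means of -0.0351 and 0.00193, adjusted p up to 0.936), and without replicate 3 its mean was -0.54 in place of -0.20. The unfolded protein list had a median of -0.10 with 22 of 30 below 0 (adjusted p = 0.00722, and adjusted p = 0.545 with an estimated correlation). In it Asns, the asparagine synthetase, stood at -0.78 (-0.38 without replicate 1) and Edem1 at 0.23. The unfolded protein list lost its call without replicate 1 or 4 (adjusted p up to 0.879). Its mean was -0.0463 without replicate 1 and -0.176 without replicate 3, in place of -0.103. In both lists 0 members passed, over all features or adjusted over the list alone. Quantile normalization and the changed sign of the Cy3 arrays each left 0 lists called at 23 h.

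No gene passed at 23 h (smallest adjusted p 0.9999). The genes nearest the threshold were Efcab10 at 1.12 (SE 0.19), Tor1aip1 at 1.69 (SE 0.36), Cysrt1 at 0.63, Ankrd40 at 0.72 and Nsfl1c at -1.03 (-0.67 without replicate 1). They were followed by the pluripotency marker Zfp42 at 0.39 (0.21 without replicate 4), Vps25 at 1.41 (0.91 without replicate 4) and the DNA repair enzyme Mutyh at -0.41. Next came Rpl34 at -0.52 (-0.16 without replicate 3) and Ost4 at -0.32. These genes had 3 arrays each except Ankrd40 with 2. Bnip3l stood at 1.01, F2r at 0.12 (-0.0169 without replicate 1) and Dntt at 0.27 (0.062 without replicate 3). Sparc stood at 0.13 (0.087 without replicate 1, 0.21 without replicate 3) and Esr1 at -0.02 (0.0576 without replicate 3). The count by limma was 0 of 16081 features (269 at an unadjusted p under 0.05), 0 with array weights, and 0 with the sign of the Cy3 arrays changed. It was 1 without replicate 3 and 27 without both arrays in doubt (0 with the Cy3 signs also changed). Of the 19 genes named at 23 h, 10 had the opposite direction with the Cy3 signs changed.

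Between times, the glycolysis list lay higher at 23 h than at 3 h, with a median difference of 0.18 and 14 of 16 members above 0 (adjusted p = 0.00282, and adjusted p = 0.426 with an estimated correlation), with Tpi1 at 0.36 and the glucose transporter Slc2a3 at 0.48. From 3 h to 23 h the cholesterol list had a median difference of 0.10 (adjusted p = 0.0466, and adjusted p = 0.426 with an estimated correlation), with Fdps at 0.36 and Tm7sf2 at 0.29. The ribosomal list had 0.08 (adjusted p = 0.0116, and adjusted p = 0.816 with an estimated correlation), with Rpl13a at 0.31 and Rpl34 at -0.43. No member passed in these lists, over all features or adjusted over the list alone. The glycolysis call held without each array in turn. The cholesterol call ended without 3 h replicate 1, 3 or 4 or 23 h replicate 3 or 4 (adjusted p up to 0.408), and the ribosomal call without 3 h replicate 2 or 3 or 23 h replicate 3 or 4 (up to 0.487). The cholesterol mean was 0.0969 in place of 0.150 without 23 h replicate 4. The ribosomal mean of 0.0562 was 0.0360 and 0.0293 without 3 h replicates 2 and 3, and 0.0955 and 0.0220 without 23 h replicates 1 and 4.

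Between 3 h and 7 h the glycolysis list differed by a median of 0.14 (adjusted p = 0.0328, and adjusted p = 0.414 with an estimated correlation) and the ribosomal list by 0.08 (adjusted p = 0.00106, and adjusted p = 0.713 with an estimated correlation). Both calls ended without 3 h replicate 3 or 7 h replicate 4, and the glycolysis call also without 3 h replicate 4 (adjusted p up to 0.629 for glycolysis and 0.256 for ribosomal proteins). Without 7 h replicate 4, an array in doubt, the glycolysis mean was 0.0366 in place of 0.170 and the ribosomal mean 0.0343 in place of 0.0809. From 7 h to 12 h, the heat shock list differed by -0.08 (adjusted p = 0.0384, and adjusted p = 0.421 with an estimated correlation). The ribosomal list differed by -0.07 (adjusted p = 2.66e-06, and adjusted p = 0.940 with an estimated correlation) and the cytoskeleton list by -0.11 (adjusted p = 0.0366, and adjusted p = 0.940 with an estimated correlation). All 3 calls ended without 12 h replicate 4. The ribosomal and cytoskeleton calls ended without 7 h replicate 4, the cytoskeleton call without 12 h replicate 1, and the heat shock call without 7 h replicate 2 or 3 (adjusted p up to 0.566, 0.566 and 0.903 for heat shock, ribosomal and cytoskeleton). Without 12 h replicate 4 their means were -0.0604, -0.0160 and -0.0465, in place of -0.112, -0.0846 and -0.0853. Without 7 h replicate 4 the ribosomal and cytoskeleton means were -0.0380 and -0.0180, and without 12 h replicate 3 the ribosomal mean was -0.128. From 12 h to 23 h the ribosomal list differed by 0.07 (adjusted p = 0.00158, and adjusted p = 0.787 with an estimated correlation), which ended without 12 h replicate 4 or 23 h replicate 4 (adjusted p up to 0.910). Its mean of 0.0599 was -0.0136 and 0.0257 without these, 0.106 without 12 h replicate 3 and 0.0992 without 23 h replicate 1. No member passed in any of these lists, over all features or adjusted over the list alone. With the sign of the Cy3 arrays changed, 0 lists were called for 23 h against 3 h, 7 h against 3 h and 12 h against 7 h, and 1 for 23 h against 12 h, ribosomal proteins at a median of -0.08.

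No single gene passed between times. For 23 h against 3 h, the nearest were Nop58 at -0.51 (SE 0.11), Nsfl1c at -1.49, Nsrp1 at 2.52 (SE 0.59), Parp16 at 0.45 and Hmgn2 at -0.35. Next came Bnip3 at 1.22 (SE 0.34), Idh3g at -0.55, Sil1 at 0.31, Serpina1d at -0.50 and Psmg2 at -1.58, all with an adjusted p of 1 by limma. The count was 0 for 23 h against 3 h (407 at an unadjusted p under 0.05), 7 h against 3 h (714), 12 h against 7 h (319), 23 h against 12 h (253) and the test of any difference among the 4 times (377). With the Cy3 signs changed it was 0 for each of these, and 9 of the 16 genes named for 23 h against 3 h had the opposite direction. Array weights called 4 for 12 h against 7 h and 0 for the other pairs. Without 12 h replicate 2, 1 feature was called for 12 h against 7 h, 1 for 23 h against 12 h and 1 among the 4 times, and without 7 h replicate 4, 3 among the 4 times. Without both arrays in doubt 11 were called for 23 h against 3 h, 1 for 23 h against 12 h and 6 among the 4 times.

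Across genes, which are not independent replicates, the mean Pearson correlation of the log2 ratios over pairs of times was 0.02 (jackknife SD 0.06 over 15 arrays). It was 0.0873 without both arrays in doubt, 1 of which was found from its outcome, with 0.0403 and 0.0527 without 7 h replicate 4 or 23 h replicate 3 alone, and lay between -0.00120 and 0.0527 without each of the 15 in turn. It was 0.0973 with the Cy3 signs changed. The pair of 7 h and 12 h had the highest, 0.11 (Spearman 0.19, covariance 0.00241), or 0.19 without both arrays in doubt, and the treated group correlated with 3 h at 0.08 and with 23 h at 0.03. Pairs of times share the 0 h reference, while the treated cells were set against non-treated cells. For pairs of times, simulated groups without change gave 0.80, 0.31 and 0.02 when the reference held a share of 0.5, 0.1 and 0 of the variance, with covariances of 0.0680, 0.0136 and 0.000763. Only the treated cells (758) and 12 h (3) had calls, and 0 were shared in the same direction. Independent calls would give 0.048 shared higher and 0.024 shared lower, so this count cannot tell whether the comparisons share a response.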

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

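The tests that weigh explanations here, the other sign patterns and splits of the arrays, and the fits that leave out or turn the arrays in doubt or change the Cy3 signs were chosen only after the results they concern were seen, whereas array weights and the arrays left out in turn were planned.

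In 9 of 142 groups of 4 arrays, 1 value stood far from the other 3, which chance gives in about 1 of 20 groups. Sec16b was 4.15 on treated replicate 2 and 0.44 to 1.02 on the others. Septin12 was -0.08 on 7 h replicate 3 against 0.69 to 0.76, Tmem252 0.391 on 7 h replicate 1 against 0.185 to 0.22, and Esr1 -0.066 on 7 h replicate 1 against 0.09025 to 0.09875. Mcl1 was -0.289 on 3 h replicate 2 against -0.218 to -0.208. On 12 h replicate 4 the ribosomal protein list had a median of -0.332 against -0.018 to -0.00583, the neutrophil list -0.346 against -0.24 to -0.221, and the deposited median was 0.008 against -0.004 to -0.002. The median absolute deviation of 3 h replicate 2 was 0.292 against 0.153 to 0.176.

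Between times, 9 list differences passed camera with the preset correlation and none with an estimated one. The ribosomal list had mean differences of 0.0809 for 7 h against 3 h, -0.0846 for 12 h against 7 h, 0.0599 for 23 h against 12 h and 0.0562 for 23 h against 3 h. The glycolysis list had 0.170 for 7 h against 3 h and 0.211 for 23 h against 3 h, and the cholesterol list 0.150 for 23 h against 3 h. The heat shock list had -0.112 and the cytoskeleton list -0.0853 for 12 h against 7 h. All except 0.211 lost their call without at least 1 array. Without 7 h replicate 4 the values for 7 h against 3 h were 0.0366 for glycolysis and 0.0343 for ribosomal proteins, and without both arrays in doubt the 1 list called there lay lower at 7 h. For 12 h against 7 h they were then -0.0380 for ribosomal proteins and -0.0180 for cytoskeleton. Without 12 h replicate 4 the heat shock, ribosomal and cytoskeleton values for 12 h against 7 h were -0.0604, -0.0160 and -0.0465, and the ribosomal value was -0.0136 for 23 h against 12 h. Without 12 h replicate 3 the ribosomal values were -0.128 for 12 h against 7 h and 0.106 for 23 h against 12 h. Without 23 h replicate 4 they were 0.0257 for 23 h against 12 h and 0.0220 for 23 h against 3 h, with 0.0969 for cholesterol. Without 23 h replicate 1 they were 0.0992 and 0.0955, and without 3 h replicates 2 and 3 the last was 0.0360 and 0.0293.

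The treated cells gave 758 called features, but their arrays vary more than those of the other groups, with a median SD between arrays of 0.30 against 0.15 to 0.16. With each array weighted by its own spread 2 features were called, the result to look for if the pooled spread is too small for these arrays, and simulated arrays without change gave 414 to 506 calls. Most of the 758 calls may therefore come from that spread. Each treated array was also held against the coefficients of the other treated arrays, over the features strongest there. The correlations across genes were -0.103, -0.228, -0.026 and 0.002 for treated replicates 1 to 4. For 12 h replicates 1 to 4 the corresponding values were 0.314, 0.112, -0.031 and 0.068. Leaving out 1 array of 4 makes the dyes of a group unequal. A dye effect of that group alone then pushes these correlations below 0. They therefore cannot decide whether the strongest features of the treated cells repeat between arrays. Over the features strongest at 3 h, the treated arrays correlated with the 3 h coefficients at 0.151 to 0.327. On the same measure 7 h replicates 1 to 4 had 0.201, 0.305, 0.255 and -0.369. The 12 h arrays had 0.001, -0.076, 0.025 and 0.397, and 23 h replicates 1, 3 and 4 had -0.027, -0.238 and 0.209. The 3 h arrays, each left out in turn, had 0.067 to 0.279. Values above 0 were therefore not special to the treated arrays. A response of the treated cells stays open. Changing the signs of the 4 arrays in other ways gave up to 817 features, and 2 of the 8 sign patterns, the real one included, gave at least 758; 8 patterns are too few for a share under 0.05.

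The arrays 7 h replicate 4 and 23 h replicate 3 ran against their groups. Over the 500 features with the strongest coefficient in the other arrays of the group, the correlation across genes was -0.471 for 7 h replicate 4, where the lowest array of the other groups had -0.166, and -0.416 for 23 h replicate 3, against -0.321, a small gap. The other arrays of their own groups, held against coefficients that include the array in doubt, had -0.207 to 0.0878 at 7 h and -0.269 to -0.0125 at 23 h, so a value below 0 is not special to these 2. Noise was weighed with a test that replaced this comparison as the one for noise after it had been seen: over the 500 features strongest at 12 h, the correlations were -0.380 and -0.393, while the other 5 arrays at 7 h and 23 h had 0.253 to 0.393 and the lowest of all other arrays had -0.080, which argues against noise alone. By these correlations, ratios that stand with the opposite sign may explain both. For 7 h replicate 4 the sign of its repeated extreme value, which does not depend on the outcome, points the same way. For 23 h replicate 3 that value is -16.61, the sign that fits its dye label, so this marker goes against opposite ratios alone there. For 23 h replicate 3, singled out by its outcome, a different response of that culture stays open and untested.

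The glycolysis list lay low at 3 h on all 4 arrays. That 1 array made the shift is argued against by the mean without any 1 of them, which reached at most -0.221 (SE 0.04 over arrays). If the 0 h reference made the whole shift, the list should lie as low at 23 h, but the mean of 23 h against 3 h was 0.211 (SE 0.04), and 0.182 without both arrays in doubt. This is weak evidence, because camera with an estimated correlation gave an unadjusted p of 0.0264 and an adjusted p of 0.426, and it leaves a partial share of the reference open: 7 h differed from 3 h by only 0.0366 without 7 h replicate 4 (0.170 with it), and the 12 h mean was also below 0, at -0.135 (-0.0968 without 12 h replicate 4). A response at 3 h stays open as a hypothesis, as does the sign reading, under which the list mean became 0.0575.

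For single times, the other sign patterns were too few for a share under 0.05. At 3 h, where 0 features were called, the highest other pattern of 8 gave 1, and 8 of 8 gave at least 0. At 7 h the real value was 0 and the highest other 33, with the sign of replicate 4 turned, and 8 of 8 patterns gave at least 0. At 12 h the values were 3 and 5, with 2 of 8 patterns at 3 or more. At 23 h they were 0 and 16, the latter with replicate 3 turned, and 4 of 4 patterns gave at least 0. The high counts with 7 h replicate 4 or 23 h replicate 3 turned point to a structure of these arrays. A real count of 0, as at 3 h, 7 h and 23 h, is reached by every pattern, so these comparisons say nothing about chance. The same holds for pairs of times, where all 35 of 35 splits gave at least the real count of 0, with highest other counts of 1 for 7 h against 3 h, 0 for 12 h against 7 h, 3 for 23 h against 12 h and 0 for 23 h against 3 h. Among the 4 times it was also 0, and 100 of 100 drawn splits gave at least that, with a highest other count of 1.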

How the results depend on the processing

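Chosen only after the data were seen were the fits without the arrays in doubt or with them turned, the fits on time-course arrays, the changed sign of the Cy3 arrays, the correlation between times without single arrays or arrays in doubt, the repeated extreme values kept, camera on all tested features, and lists under scaling and quantile normalization; the other alternatives were planned before.

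The number of arrays limits the precision of these results, and signal over background was not used here. The reading of the signs decides the direction of 81 of the 154 named values, and the counts of calls did not keep their size. Where the construction of a setting does not show it, the cause was not tested. The alternatives fixed in advance were run. The orientation rule fixed in advance was not followed, and fewer list members were named than planned. Fits on a single dye at 23 h leave 1 array in Cy5, which is assumed to vary like the other groups.

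Counts of called features by setting, with the values of the report in parentheses, were as follows. With arrays scaled to the same spread the treated count was 5 (758), that for 12 h against 7 h 2 (0) and that among the 4 times 2 (0). With quantile normalization these were 3, 2 and 2, with 5 at 12 h (3) and 2 for 23 h against 12 h (0). Array weights gave 2 for the treated cells, 3 at 3 h (0), 42 at 12 h and 4 for 12 h against 7 h. With only the arrays of the groups compared there were 0 in the treated cells, 0 at 12 h and 2 for 23 h against 12 h. A limit of 1.5-fold left 264 of the treated calls. Without a filter on missing values there were 9 at 12 h, 7 for 12 h against 7 h, 2 for 23 h against 12 h and 2 among the 4 times, and with only features measured on every array 0 at 12 h, where Clk4 is not measured on every array. Without the dye term there were 2 for 12 h against 7 h.

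With only the arrays that have the own RNA in Cy3, there were 488 calls in the treated cells, 1 at 12 h, 1 for 12 h against 7 h and 1 for 23 h against 12 h. With only Cy5 there were 0 at 12 h, 1 at 23 h (0), 1 for 23 h against 12 h, 1 for 23 h against 3 h (0) and 1 among the 4 times. With the sign of the Cy3 arrays changed the treated count was 1313. Leaving out both arrays in doubt as well gave 1170 in the treated cells, 2 at 7 h, 2 at 12 h and 0 elsewhere. Changed Cy3 signs with array weights gave 34 in the treated cells, 614 at 12 h, 1 at 7 h, 2 at 23 h, 1 for 12 h against 7 h, 4 for 23 h against 12 h, 1 for 23 h against 3 h, 1 among the 4 times and 0 at 3 h and for 7 h against 3 h.

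Without both arrays in doubt the counts were 18 at 3 h, 35 at 7 h (0), 26 at 12 h, 27 at 23 h, 1 for 23 h against 12 h, 11 for 23 h against 3 h and 6 among the 4 times. With both turned they were 24, 97, 35 and 63 at 3, 7, 12 and 23 h, 1 for 7 h against 3 h (0), 4 for 23 h against 12 h, 13 for 23 h against 3 h and 15 among the 4 times. On time-course arrays only, without both, they were 16, 77, 40 and 59 at the 4 times, 1 for 12 h against 7 h, 2 for 23 h against 12 h, 12 for 23 h against 3 h and 7 among the times. On time-course arrays only, with both turned, they were 39, 214, 68 and 124, with 5 for 7 h against 3 h, 2 for 12 h against 7 h, 4 for 23 h against 12 h, 30 for 23 h against 3 h and 18 among the times. Turning an array adds its values to the group's mean, so a higher count is built in if the array was turned wrongly in the deposit, and also if it was chosen for its outcome.

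With the replicate number as a block, the treated count was 606, that at 12 h 3 and that of every other comparison 0. Lists kept their counts except for 23 h against 3 h, with 2 in place of 3. Same-numbered arrays of different groups had a mean correlation of their deviations of 0.029 across genes, with 4 of 36 pairs over 0.1. Pairs with other numbers and the same dye had 0.044, also with 4 of 36 over 0.1. The numbers thus gave no sign of pairing. Over all probes, even arrays of the same group and dye had a mean Pearson correlation of only 0.098. This check therefore cannot exclude shared cultures or RNA.

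Counts of called lists moved as follows. With an estimated correlation all were 0 (treated 5, 3 h 6, 7 h 1, 12 h 10, 23 h 2, 7 h against 3 h 2, 12 h against 7 h 3, 23 h against 12 h 1, 23 h against 3 h 3). With fry the treated count was 9 and the others 0. Without the dye term there were 4 at 23 h, 0 for 23 h against 12 h and 1 for 23 h against 3 h. Quantile normalization gave 0 at 23 h, and camera on all tested features 1 for 7 h against 3 h. On time-course arrays only there were 5 at 12 h, 1 at 23 h, 1 for 7 h against 3 h, 1 for 12 h against 7 h and 1 for 23 h against 3 h. Without both arrays in doubt there were 9 in the treated cells, 10 at 7 h, 10 at 23 h, 1 for 7 h against 3 h, 1 for 12 h against 7 h, 5 for 23 h against 12 h and 7 for 23 h against 3 h. With both turned these were 10, 12, 8, 1, 0, 3 and 5, with 10 at 3 h. On time-course arrays only, without both, there were 8 at 7 h, 8 at 23 h, 1 for 7 h against 3 h and 0 for 12 h against 7 h. With both turned there were 14, 8, 1 and 0, and 2 for 23 h against 12 h. With the sign of the Cy3 arrays changed there were 0 at 3 h, 7 h and 23 h, 2 at 12 h, and 0 for 7 h against 3 h, 12 h against 7 h and 23 h against 3 h.

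The changed sign of the Cy3 arrays also turned the direction of 22 called lists, of 33, so their directions rest on that reading. List means became 0.0392 for cholesterol (-0.21) and 0.00881 for glycolysis (-0.29) in the treated cells. At 3 h they were -0.00793 for G2 and M phase, -0.0206 for cholesterol, whose rank among all genes turned, 0.0391 for ribosomal proteins, 0.0575 for glycolysis and 0.0432 for cytoskeleton. At 12 h they were 0.0393 for neutrophil genes, 0.0195 for interleukin-3 targets, 0.0420 for the unfolded protein response, 0.0691 for ribosomal proteins, 0.0362 for glycolysis and 0.0457 for cytoskeleton. For 7 h against 3 h they were -0.0236 for ribosomal proteins and -0.135 for glycolysis. For 12 h against 7 h they were 0.0418 for heat shock, 0.0536 for ribosomal proteins and 0.0647 for cytoskeleton. For 23 h against 12 h the ribosomal mean was -0.0815, and for 23 h against 3 h the means were -0.0397 for cholesterol, -0.0514 for ribosomal proteins and -0.124 for glycolysis.

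The changed sign of the Cy3 arrays turned the direction of 81 of 154 values of named genes, among them 24 of the 38 that had been called. Of the 38, 3 stayed past the threshold, all 3 in the opposite direction. Named genes were chosen by their values under the deposited signs, so these counts are largely built in and do not weigh the 2 readings. The turned values were as follows. In the treated cells they were Ell -1.69, Glrx5 -0.86, Retreg2 -0.31, Actn2 -1.09, Papolb -1.51, Klhdc7a -1.22, Fam170b -0.90, Psmb8 1.52, Selenbp2 0.039, Bdh2 0.28, EG245190 1.15, Bnip3 0.32, Mbd4 0.58 and Ddx55 0.51. In the treated cells there were also Ndrg1 0.31, Gp5 -0.15, Lox 0.0442, Incenp -0.0563, Srebf2 0.008, Hmgcs1 0.18, Atp5k -0.0405, Slc2a3 0.26 and Pgam1 0.15. At 3 h they were Bnip3 0.33, Scd2 0.0391, Pgm1 0.30, Selenbp1 0.0307, Selenbp2 0.26, Ndrg1 0.12, Hba-a1 0.043, Rpl7 0.0348, Tpi1 0.0879, Pgam1 0.11 and Esr1 0.0867. At 7 h they were Fbxl12 0.0885, Acadvl 0.13, Tchp -0.54, Cldn3 0.0805, Zdhhc15 -0.20, Lin7a 0.0525, Col3a1 -0.0948 and Esr1 -0.0418. At 12 h they were Clk4 -1.01, Pank1 -0.16, Ftsj3 0.12, S100a8 0.20, Mmp8 0.0377, Lyz2 0.045, Nfe2 0.0325, Vwf 0.0945, Dntt 0.0455, Klf2 0.014, Klf6 0.0257, Pim1 0.16, Mcm6 -0.024 and Slc7a5 0.0253. At 12 h there were also Rps15a 0.0532, Rps27 0.00375, Ndufa2 -0.17, Atp5b -0.076, Gapdh 0.12 and Esr1 -0.0399. At 23 h they were Efcab10 -0.24, Tor1aip1 -1.05, Zfp42 -0.25, Vps25 -0.76, Mutyh 0.18, Rpl34 0.37, Ost4 0.0805, Dntt -0.27, Edem1 -0.0209 and Esr1 0.0809. For 23 h against 3 h they were Nsfl1c 0.18, Hmgn2 0.0209, Bnip3 -0.41, Psmg2 0.75, Fdps -0.20, Rpl13a -0.0313, Rpl34 0.37, Tpi1 -0.0739 and Slc2a3 -0.44.

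Of the named genes with their comparisons, 36 lost their call with arrays scaled to the same spread, 37 with quantile normalization, 37 with array weights, where 14 gained it, and 38 with only the arrays of the groups compared. Scaling and quantile normalization turned the direction of 0 named genes and 0 called lists, and ended the calls of 3 and 6 lists.

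Under the other settings few named genes changed direction. On Cy3 arrays alone Vwf at 7 h was -0.000667, F2r at 23 h -0.0375 and Esr1 in the treated cells 0.0696. On Cy5 arrays alone Vwf at 12 h was 0.0025 and Esr1 0.0304, -0.00425 and 0.105 at 3, 12 and 23 h. Esr1 at 23 h was also 0.0151 with only the arrays of that group, 0.0523 without centring, and 0.0576 without both arrays in doubt, on all arrays or on time-course arrays only. The contrast of 7 h against 3 h correlated with that of 23 h against 12 h at -0.0441, a single correlation and not a mean. The mean correlation over pairs of times (0.02) was 0.113 with both arrays in doubt turned and 0.0973 with the sign of the Cy3 arrays changed. It was 0.0873 without both arrays in doubt and ranged from -0.00120 to 0.0527 without each array in turn.

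Leaving out each array in turn, the counts ranged from 836 to 1396 in the treated cells, 0 to 0 at 3 h, 0 to 4 at 7 h, 1 to 6 at 12 h and 0 to 1 at 23 h. They ranged from 0 to 0 for 7 h against 3 h and 23 h against 3 h, 0 to 1 for 12 h against 7 h and 23 h against 12 h, and 0 to 3 among the 4 times. Called lists ranged from 2 to 5 in the treated cells, 4 to 5 at 3 h, 0 to 9 at 7 h, 4 to 8 at 12 h and 0 to 8 at 23 h. They ranged from 0 to 5 for 7 h against 3 h, 0 to 4 for 12 h against 7 h, 1 to 4 for 23 h against 12 h and 1 to 5 for 23 h against 3 h. The highest counts of the time course came without an array in doubt for lists at 7 h and 23 h. Ranges that crossed 0 were -0.61 to 0.0896 for S100a8, -0.0169 to 0.30 for F2r, -0.11 to 0.06 for Esr1 and -0.54 to 0.00193 for the neutrophil list, all at 23 h, and -0.12 to 0.00811 for Esr1 at 3 h.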

Other observations

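The fit without both arrays in doubt, the comparisons of its calls, the changed Cy3 signs, and the settings other than the first for HIF targets were chosen only after the data were seen; the tests of HIF targets were written before their result, on a hypothesis taken from genes of the same arrays.

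Without both arrays in doubt, limma called genes of neutrophil granules at 23 h, where the full data called none. Ltf, the lactoferrin gene, fell by 1.26 (SE 0.11, adjusted p = 0.000182, against -0.54 with all arrays). The cathelicidin gene Camp fell by 1.20 (adjusted p = 0.000402), Mmp8 by 1.11 (adjusted p = 0.00148), the elastase gene Elane by 0.94 (adjusted p = 0.000552) and Mpo, the myeloperoxidase gene, by 0.91 (adjusted p = 0.000402). Glud1, the glutamate dehydrogenase, rose by 1.35 at 23 h (adjusted p = 0.000182) and by 1.20 at 12 h (adjusted p = 1.30e-05). At 12 h Mmp8 fell by 0.76 (adjusted p = 0.00273) and Elane by 0.49 (adjusted p = 0.00866), and Smc4 rose by 0.73 (adjusted p = 0.00103). At 23 h only 2 arrays remained. Of the arrays left out, 1 was found through its outcome, so these calls are conditional on that choice. Without 23 h replicate 3 alone, Ltf also stood at -1.26 (adjusted p = 0.0950 by limma), and 1 feature was called at 23 h. The further calls came with leaving out 7 h replicate 4 as well. That array enters at 12 h and 23 h only through the shared spread and dye term. No array at 12 h was left out. The calls at both times also rest on the reading of the signs. With the Cy3 signs changed in the fit without both arrays there were 0 calls at 23 h and 2 at 12 h, none shared. At 23 h Ltf, Camp, Mmp8, Elane, Mpo and Glud1 then stood at 0.0767, 0.16, 0.15, 0.16, 0.0118 and -0.18. At 12 h Glud1, Mmp8, Elane and Smc4 stood at 0.0434, 0.0377, -0.0133 and 0.041.

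At 3 h the same fit called Bnip3 at -1.38 (SE 0.11, adjusted p = 8.07e-05), Ndrg1 at -1.15 (SE 0.09, adjusted p = 9.76e-05) and Selenbp2 at -1.06 (SE 0.10, adjusted p = 0.000309). It also called Fam162a at -0.71 (adjusted p = 0.00583), the metallothionein Mt1 at -0.71 (adjusted p = 0.0122), Fdps at -0.48 (adjusted p = 0.0142) and the aldolase Aldoa at -0.52 (adjusted p = 0.0357). At 7 h it called Ndrg1 at -1.24 (adjusted p = 0.000299), Glud1 at 1.03 (adjusted p = 0.000299) and Camp at -0.71 (adjusted p = 0.00639). No array at 3 h was left out, so values there are those of the full data and only the spread is smaller. With the Cy3 signs changed in this fit 0 features were called at 3 h. Bnip3, Ndrg1, Selenbp2, Fam162a, Mt1, Fdps and Aldoa then stood at 0.33, 0.12, 0.26, 0.15, 0.129, -0.0452 and 0.0578. At 7 h 2 were called, neither of them among the 35, and Ndrg1, Glud1 and Camp stood at 0.0499, 0.00342 and 0.0665.

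Bnip3, Ndrg1 and several glycolysis genes are targets of the hypoxia-inducible factor HIF, so a lower HIF response at 3 h and in the treated cells is a hypothesis. It was tested on 16 other HIF targets. Of these, 1, Lox, matched a symbol in a fixed list, and Ero1a stands in the unfolded protein list under its older symbol Ero1l, which was not matched. Their mean was -0.166 at 3 h (15 of 16 below 0) and -0.285 in the treated cells (11 of 16 below 0), with an unadjusted p of 0.0143 and 0.0216 by camera with an estimated correlation, both 0.0216 adjusted over these 2 tests. At 3 h no member passed over all features (smallest adjusted p 0.887 by limma). The lowest there were Ddit4 at -0.46 and Higd1a at -0.44, while Rora, Lox and P4ha1 lay next to 0, at -0.001, -0.004 and -0.013. In the treated cells the lowest were Ero1a at -0.92, Gys1 at -0.88, Egln1 at -0.72 and Kdm4b at -0.62. Members above 0 were Egln3 at 0.299, P4ha1 at 0.195, Mxi1 at 0.130, Stc2 at 0.107 and Pam at 0.080. At 7, 12 and 23 h the means were -0.0600, -0.0971 and -0.0511, and camera with an estimated correlation gave an unadjusted p of 0.341, 0.128 and 0.537. At 7 h the array in doubt, replicate 4, had a mean of 0.244 and the others -0.0737, -0.141 and -0.269. Without it the 7 h mean was -0.172 (unadjusted p of 0.000538 by camera), and without replicate 3 it was 0.0123. Without both arrays in doubt the means were -0.174, -0.0971 and -0.104 at 7, 12 and 23 h (unadjusted p of 0.000464, 0.00477 and 0.0313 by camera). These values are conditional on leaving out an array found from its outcome. A lower mean is therefore not shown to be limited to 3 h, and no difference between times was tested. Values of -0.166 and -0.285 are consistent with the hypothesis. Single arrays moved the p past 0.05 but the mean little. Without treated replicates 1, 2 and 3 the means were -0.237, -0.288 and -0.282, and camera with an estimated correlation gave an unadjusted p of 0.0858, 0.0579 and 0.0558. Without 3 h replicate 3 the mean was -0.143 and camera gave an unadjusted p of 0.0530. Means of single treated arrays lay between -0.301 and -0.268. With the Cy3 signs changed, the means were 0.00665 in the treated cells and 0.0798 at 3 h, with an unadjusted p of 0.796 and 0.407. At 7, 12 and 23 h they were then -0.0474, 0.0222 and -0.0599.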
